A study of Arabidopsis thaliana with 9 samples.

How the data were processed

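The samples are 9 single-channel Affymetrix Arabidopsis arrays of whole 3-day seedlings, 3 each of untransformed Col-0, SPL13 transformants and mSPL13 transformants. Per the labels, the 3 arrays of a genotype are independent biological replicates from independent seed lots. Per the labels' protocols, seeds spent 3 days in the dark at 4 °C and 3 days in light at 22 °C on medium with 1% sucrose, RNA was extracted with phenol and SDS and checked on a Bioanalyzer, and total RNA was made into cDNA and biotin-labelled cRNA by T7 transcription. The deposited values are intensity signals on a linear scale, made by the authors with the GCOS implementation of MAS5 (per the submitters' processing notes). In 3 arrays 1 probe set had a signal of 0. On every array the trimmed mean of the signals was 499.8, so all arrays carry the same global scaling. How the transgenic lines were selected is not given in the sources used here. Detection calls and scanner files were not used here.

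Gene names came from the table that pairs the platform's probe sets with genes. Of the 22810 probe sets, 64 are controls, 13513 pair with 1 gene, 503 with several and 8730 (38.4%) have no gene listed in it. Of the 13513, 13436 were found in the TAIR10.1 gene table, which was used for names and for which genes neighbour each other. Probe sets that pair with several genes were tested and counted, and not named as a gene. The gene lists hold 395 genes. The table names a probe set for 64 members, and 45 were tested. A probe set of several genes that are all in a list counted as 1 member.

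Signals were transformed as log2(signal + 20.7), where 20.7 is the 20th percentile of all values. Probe sets with a mean log2 value above 6.922 (the 40th percentile) were kept, which left 13647. A model with 1 mean per genotype was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (6 residual and 7.92 prior degrees of freedom, with a trend of the variance on mean signal). The contrasts were mSPL13 versus SPL13, mSPL13 versus Col-0, SPL13 versus Col-0, and mSPL13 versus the mean of SPL13 and Col-0. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Every p of a named gene is from limma. Errors are SD over the 3 arrays for signals and the moderated SE for log2 fold changes. The number of arrays limits the precision.

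The named genes followed a fixed rule. In each comparison they were the 10 probe sets of 1 gene in the TAIR10.1 table with the largest rise and the 10 with the largest fall among those called with non-overlapping groups (5 each way for SPL13 versus Col-0), every measured SPL gene, and up to 4 tested members per other gene list with the smallest p. A further 10 each way were those called in both mSPL13 comparisons with the highest and lowest mean change. Groups do not overlap by chance in 10% of 3 against 3 splits. The 22 gene lists, the thresholds, the comparisons and the alternatives were set before the data were examined. The 28 families grouped by symbol or by chromosome, chloroplast-encoded genes among them, were defined after the probe annotation was seen and before any fold change was computed. Lists with at least 3 tested members and families with at least 5 were tested with camera, with a preset inter-gene correlation of 0.01 and with an estimated one, and adjusted within each comparison, with lists and families apart. No probe set paired with the lists of SPL genes targeted by miR156, CIN-type TCP factors and morning clock genes, and these were not analysed here. Members named for the lists of seed storage and late embryogenesis, trichome regulators, jasmonate response, and salicylic acid and immune response did not reach the test.

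The pipeline was tested on simulated data, drawn at the real means and spread with changes added to known probe sets. For mSPL13 versus SPL13 it recovered 47.8% of probe sets changed 1.5-fold, 97% at 2-fold and 100% at 4-fold, and 3.6% of its calls were unchanged probe sets. For mSPL13 versus Col-0 these were 40.3%, 100%, 100% and 6.4%, for SPL13 versus Col-0 47.8%, 97%, 100% and 4.7%, and for mSPL13 versus both 65.7%, 100%, 100% and 3.8%. Each probe set was drawn independently, so the shares of unchanged probe sets among the calls do not account for genes that vary together.

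The alternatives were other pseudocounts (10th and 40th percentile, and none), no filter and a stricter one (60th percentile), quantile normalization, median centring, eBayes without trend, a fit on the compared groups only, the replicate number as a block, array quality weights, each array left out in turn, other thresholds, an estimated correlation, and all probe sets of a list's genes. A fit without the chloroplast-encoded probe sets was added after seeing the data. Ratios of 3' to 5' control signals were compared with two-sided exact permutation tests, adjusted over 12 tests. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.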

Results

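RNA from whole 3-day Arabidopsis thaliana seedlings was measured on 1-colour Affymetrix arrays in 3 genotypes with 3 arrays each. The genotypes were the untransformed wild type Col-0, seedlings transformed with a non-mutated SPL13 gene under its native promoter (called SPL13 here), and seedlings transformed with a form of the gene that is resistant to the microRNA miR156 (called mSPL13). SPL13 encodes a transcription factor of the SQUAMOSA-PROMOTER-BINDING PROTEIN-LIKE family, and miR156 is a microRNA that represses several genes of this family. The 3 arrays of each genotype came from independent seed lots. The median signal of an array was between 175.6 and 190.8. The log2 signals of any 2 arrays correlated at 0.959 to 0.988 across the 13647 probe sets tested. The number of arrays limits the precision of every value below.

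AT1G76580 (SPL16), an SPL gene that miR156 does not target, had mean signals of 118.4 in Col-0, 134.4 in SPL13 and 107.9 in mSPL13, and no comparison passed the test. The level of SPL13 and of the other SPL genes targeted by miR156 was not analysed here, because no probe set carried their names. Among the control probe sets, the ratio of 3' to 5' signal, which rises as RNA breaks down, was 1.05 ± 0.0494 (SD, n = 3) for GAPDH in mSPL13 against a mean of 0.964 in the other 6 arrays (two-sided exact permutation p = 0.048, adjusted p = 0.3 over 12 tests of such ratios). The ratio was 1.21 against 1.09 for ubiquitin (exact permutation p = 0.071, adjusted p = 0.3) and 2.87 against 2.59 for actin (exact permutation p = 0.31, adjusted p = 0.531). With 3 arrays against 3, the smallest p such a test allows is 0.1.

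The comparison of mSPL13 with SPL13 asks what changes when the transgene escapes miR156. The gene with the largest rise was AT4G19430, whose signal was 2566 ± 229 (SD, n = 3) in mSPL13, 6.0 ± 6.97 in SPL13 and 11.3 ± 15.6 in Col-0. AT5G55450, of the lipid transfer protein family, rose 4.55-fold to 904 ± 88.1, AT5G55180, of the glycosyl hydrolase family, rose 3.25-fold to 4976 ± 172, and OSM34, an osmotin-like protein, rose 2.98-fold to 397.5 ± 212. AT1G01390, a UDP-glycosyltransferase, fell by 2.26 ± 0.27 (SE) on the log2 scale, from 236 ± 92.5 in SPL13 to 32.6 ± 16.6. MSRB6, a methionine sulfoxide reductase, fell by 1.65 ± 0.27 to 504 ± 30.8.

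In all, 254 probe sets were higher and 160 lower in mSPL13 than in SPL13 (limma, adjusted p under 0.05), of which 87 and 28 differed by at least 2-fold. Apart from AT4G19430, the nuclear genes named as risen here and above were chosen because both mSPL13 comparisons called them. AT2G47780, among the falls below, was chosen likewise. Further nuclear genes that rose were AT1G62500 (log2 fold change 1.52 ± 0.16), AT3G13175 (1.35 ± 0.22), AT1G19530 (1.34 ± 0.26), GAT1_2.1, a class I glutamine amidotransferase (1.28 ± 0.21), and AT3G15450 (1.08 ± 0.21). Further genes that fell were AT5G57760 (-1.99 ± 0.31), AT1G06830, of the glutaredoxin family (-1.57 ± 0.23), AT1G67910 (-1.41 ± 0.19), AT5G44580 (-1.38 ± 0.22), AT1G28600, a GDSL-type lipase (-1.37 ± 0.15), AT3G59340 (-1.32 ± 0.18), AT1G73120 (-1.29 ± 0.13), AT5G62280 (-1.23 ± 0.28) and AT2G47780, of the rubber elongation factor family (-1.15 ± 0.24). The mean AT4G19430 signals of SPL13 and Col-0 lie below the pseudocount of 20.7, so its log2 fold change of 6.63 ± 0.28 is set by that choice. It was 4.64 with the pseudocount at the 40th percentile, and with the pseudocount at the 10th percentile, with none or with the stricter filter the gene was not among the probe sets tested. The log2 fold change of AT1G01390 was -1.31 with the pseudocount at the 40th percentile and -2.95 with none. The count of 414 calls fell to 236 with no filter on low signal, and it was 252 without SPL13 replicate 1, 213 without SPL13 replicate 3, and 210, 254 and 200 without mSPL13 replicates 1, 2 and 3. With array quality weights the count was higher than 414. The calls of AT2G47780 and OSM34 were each lost without SPL13 replicate 2, SPL13 replicate 3, mSPL13 replicate 1 or mSPL13 replicate 3 (log2 fold changes of -1.20 to -0.85 and 1.19 to 1.72), and that of AT5G62280 without SPL13 replicate 1 or 3 or mSPL13 replicate 2 or 3 (-1.31 to -0.99). AT3G15450 was lost without SPL13 replicate 2 or mSPL13 replicate 3 (0.94 to 1.06), and AT1G19530 without mSPL13 replicate 2 (1.17). With no filter on low signal these 5 calls were lost too, and that of OSM34 also without trend.

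Chloroplast-encoded genes made up 48 of the 254 probe sets that were higher in mSPL13 than in SPL13. Of the 66 such genes tested, 48 rose and 0 fell (58 rose when adjusted over the list alone), and the median log2 fold change was 1.61. Without mSPL13 replicate 3, 27 rose. The largest rises were those of psbB, which encodes a photosystem II protein (log2 fold change 3.67 ± 0.54, signal 202 in SPL13 and 2972 in mSPL13), psbA (3.63 ± 0.55), rpoC1, a subunit of the plastid RNA polymerase (3.35 ± 0.43), and psbT (3.20 ± 0.31). The genes psaA, rpl20, petL, rbcL and atpF followed, between 2.89 and 2.51, and the calls of psaA (without mSPL13 replicate 2 or 3) and atpF (without mSPL13 replicate 1 or 3) were lost when 1 array was left out (2.74 to 2.86 and 2.29 to 2.36). Without SPL13 replicate 1 the values of rpoC1, psaA and atpF were 2.67, 1.95 and 1.86, and with the pseudocount at the 40th percentile that of psbT was 2.44. With no filter on low signal the calls of psaA and atpF were lost. Against all other genes the set had a camera adjusted p of 1.03e-50 with a preset correlation, and adjusted p = 0.33 with an estimated correlation. The difference lies in the SPL13 arrays: their chloroplast medians were -2.35, -0.99 and -0.80 relative to the Col-0 mean, against 0.15, -0.03 and 0.30 in mSPL13. The 4 mitochondrially encoded probe sets tested moved with them, and all 4 rose in mSPL13 against SPL13, with a median of 2.1. Part of this lies in mSPL13: against Col-0 all 4 were positive there, with a median of 0.68, and 0 passed. Their medians in single Col-0 arrays ranged from -0.614 to 0.692. The 8 nuclear photosynthesis genes tested, among them PRK, RCA and LHCB4.2, had a median of -0.06, and 0 passed. Without the chloroplast-encoded probe sets, a choice made after seeing the data, the fit called 200 probe sets higher and 161 lower.

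**Figure D1:**
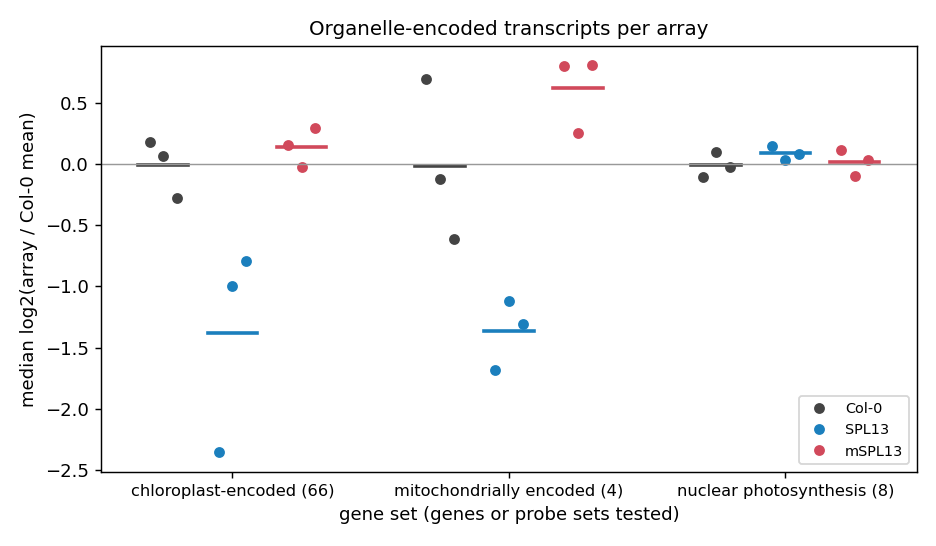
Median log2 ratio of each array to the Col-0 mean (y axis) for the 66 chloroplast-encoded genes, 4 mitochondrially encoded probe sets and 8 nuclear photosynthesis genes (x axis); points are single arrays and bars are group means. The 3 SPL13 arrays lie at -0.80 or lower for the chloroplast genes, and all 9 arrays lie between -0.11 and 0.15 for the nuclear photosynthesis genes.

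Gene lists chosen before the data were examined gave few nuclear groups in this comparison. The aliphatic glucosinolate genes (BCAT4, AT2G31790 and GSTU20) had 0 members that passed over all genes and 2 that were lower when adjusted over the list alone, with a median of -0.47 (camera adjusted p = 0.0158, and adjusted p = 0.214 with an estimated correlation). The cell division list (AUR1, AUR2 and PRL) also had 0 that passed over all genes and 2 higher when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.0158, and adjusted p = 0.214 with an estimated correlation). Each of these 2 lists held 3 tested members, and their calls were lost without SPL13 replicate 3 (adjusted p = 0.0807 and 0.054) or mSPL13 replicate 2 (0.0794 for both). NAI2, which is needed for endoplasmic reticulum bodies in seedlings and roots, fell by 0.60 ± 0.11 (limma adjusted p = 0.0097), a call lost without mSPL13 replicate 1 (-0.53), and the other 3 root markers tested did not pass, among them PYK10 (log2 fold change 0.04 ± 0.09). The lists for flavonoid synthesis, expansins and xyloglucan endotransglucosylases, heat shock, seed oil mobilisation, and shoot meristem and leaf patterning were not called and had 0 members that passed over all genes. Adjusted over the list alone, EXPA8 and EXPA15, the heat shock genes HSP17.6B and ROF2, and YAB5 of the leaf patterning list were lower. COR47, GH3.3, GH3.5, GI, GID1A and GID1B, from lists with under 3 tested members, did not pass in this or the other comparisons.

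Families grouped by gene symbol, chosen after the probe annotation was seen and before any fold change was computed, added single members, named because they were called. SWEET3, a sugar transporter, rose by 1.08 ± 0.21 on the log2 scale, BGLU44 by 0.79 ± 0.12 and EXLB1, an expansin-like gene, by 0.59 ± 0.12. IAA20, of the auxin-responsive Aux/IAA family, fell by 1.2 ± 0.20, BZIP61 by 1.16 ± 0.16 and UGT76C2, a cytokinin glucosyltransferase, by 0.98 ± 0.15. The 16 trichome birefringence-like genes had a median of -0.19, with 0 members that passed (camera adjusted p = 0.0361, and adjusted p = 0.548 with an estimated correlation).

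The comparison of mSPL13 with Col-0 sets the resistant form against untransformed seedlings. Among the probe sets with a gene name, AT4G19430 had again the largest rise (log2 fold change 6.44 ± 0.28, against a mean Col-0 signal under the pseudocount, and 4.58 with the pseudocount at the 40th percentile), followed by AT5G55450 (2.62 ± 0.19) and OSM34 (2.07 ± 0.38, and 1.43 with that pseudocount). DFR, the dihydroflavonol reductase of anthocyanin synthesis, fell by 1.47 ± 0.34, from 475 in Col-0 to 143.8 in mSPL13. The cell wall-loosening expansin EXPA8 fell by 1.28 ± 0.28, from 849 to 339.5. AT1G01390 had the largest fall, by 2.94 ± 0.27, with a value of -1.84 with the pseudocount at the 40th percentile and -3.67 with none.

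Of the 13647 probe sets, 282 were higher and 314 lower in mSPL13 than in Col-0 (limma, adjusted p under 0.05), of which 58 and 68 differed by at least 2-fold. GAT1_2.1 rose 3.43-fold, AT1G62500 3.21-fold, AT1G19530 3.07-fold, AT3G15450 3.07-fold to 7278 ± 321, AT5G55180 2.99-fold and AT3G13175 2.77-fold. AT5G61590, the ERF factor DEWAX that represses wax synthesis, rose 3.25-fold, from 655 ± 524 to 1805 ± 38.5, and its SPL13 signal was 1409 ± 206. AT2G47780 was 3.41-fold lower, MSRB6 3.3-fold lower and AT1G80130 2.99-fold lower in mSPL13. AT1G67910, AT1G28600, AT5G57760, AT3G59340, AT1G73120 and AT5G59130, a subtilase, fell by 1.45 to 1.56 on the log2 scale. With the pseudocount at the 40th percentile, AT5G59130 was at -0.86 and AT1G80130 at -0.97. The count of 596 was 331, 248 and 903 without Col-0 replicates 1, 2 and 3, and 293 and 307 without mSPL13 replicates 1 and 3. With no filter on low signal, fewer than 314 probe sets were lower. The call of AT5G61590 was lost without Col-0 replicate 1 or 2 (1.37 to 1.43, and 2.29 without Col-0 replicate 3), and those of AT5G57760 and AT1G06830 without Col-0 replicate 2 or mSPL13 replicate 1 or 3 (-1.53 to -1.34 and -0.997 to -0.90). These 3 calls were lost with no filter on low signal too.

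Of the 4 flavonoid pathway genes tested, DFR and the anthocyanin glucosyltransferase AT4G14090 (-1.44 ± 0.29) fell in mSPL13 against Col-0, and UF3GT (-1.14 ± 0.34) and UGT78D2 (-0.61 ± 0.20) did not pass over all genes, while all 4 were lower when adjusted over the list alone. The call of DFR was lost without Col-0 replicate 1 or 2 or mSPL13 replicate 1 or 3 (-1.38 to -1.11), and that of AT4G14090 without Col-0 replicate 1 or 2 or mSPL13 replicate 1 (-1.28 to -1.22). Both were lost with no filter on low signal. The median was -1.29 (camera adjusted p = 0.000361, and adjusted p = 0.131 with an estimated correlation). Within Col-0 the list median was 0.38, 0.50 and -0.88 for replicates 1, 2 and 3, so Col-0 replicate 3 lay within the range of the SPL13 arrays (-0.89 to -0.58) and at the upper end of the mSPL13 arrays (-1.45 to -0.88).

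**Figure D2:**
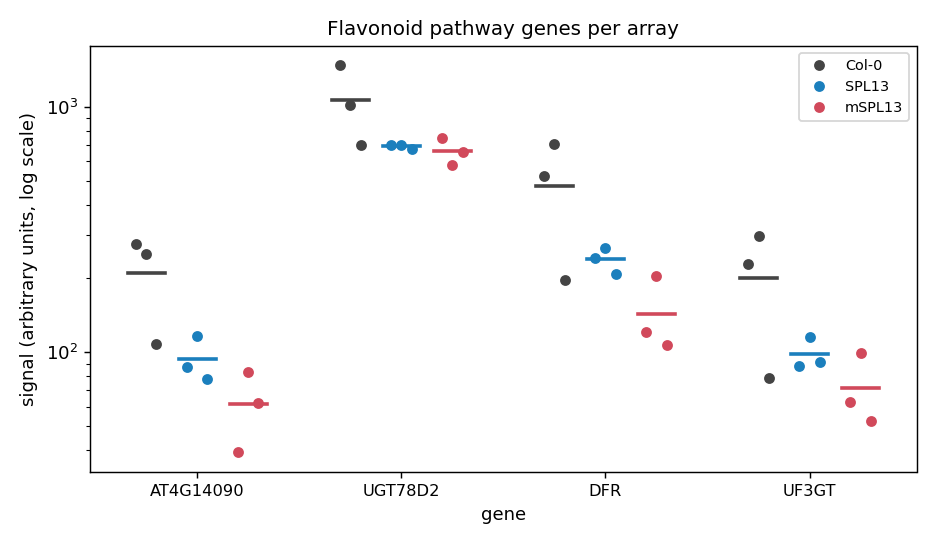
Signals of the 4 flavonoid pathway genes tested (x axis) on a log scale in arbitrary units (y axis); points are single arrays and bars are means of 3 arrays per genotype. DFR averaged 475 in Col-0, 239 in SPL13 and 143.8 in mSPL13, and Col-0 replicate 3 gave 197.0.

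Of the 3 aliphatic glucosinolate genes, BCAT4, which starts methionine chain elongation (-1.25 ± 0.29), and the glucosyltransferase AT2G31790 (-0.62 ± 0.13) fell, and GSTU20 (-0.37 ± 0.12) was lower only when adjusted over the list alone, in which all 3 passed (camera adjusted p = 0.00114, and adjusted p = 0.131 with an estimated correlation). Of 3 cell division genes, AUR2, an Aurora kinase of mitosis, rose (0.43 ± 0.11), while AUR1 (0.43 ± 0.12) and PRL (0.07 ± 0.14) did not pass (camera adjusted p = 0.0389, and adjusted p = 0.131 with an estimated correlation). Adjusted over the list alone, 2 of the 3 were higher. Of 5 expansin and xyloglucan endotransglucosylase genes, EXPA8 and EXPA15 (-0.80 ± 0.16) fell (2 lower and 1 higher when adjusted over the list alone), and XTH33 (0.65 ± 0.26) and EXPA4 (-0.25 ± 0.18) did not pass over all genes (camera adjusted p = 0.0389, and adjusted p = 0.131 with an estimated correlation). Of 4 root markers, NAI2 fell (-0.67 ± 0.11) and PYK10 (-0.07 ± 0.09), EXPA7 (-0.09 ± 0.18) and EXPA18 (-0.50 ± 0.15) did not pass, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.138 with an estimated correlation). SMZ, an AP2-type floral repressor, fell by 0.53 ± 0.14 (limma adjusted p = 0.0443). The calls of SMZ and AUR2 were each lost in 8 of the 9 fits that leave out 1 array, all but that without Col-0 replicate 3 (-0.56 to -0.44 and 0.39 to 0.47). Both were lost on the compared groups only and with the replicate number as a block. SMZ was also lost with no filter on low signal, and AUR2 also with quantile normalization or without trend. BCAT4 and EXPA8 were lost with no filter, and BCAT4 with array quality weights. EXPA8 was lost without Col-0 replicate 1 or 2 or mSPL13 replicate 1 or 3 (-1.33 to -0.97), EXPA15 without mSPL13 replicate 3 (-0.73), BCAT4 without Col-0 replicate 1 or mSPL13 replicate 2 or 3 (-1.14 to -0.95) and AT2G31790 without Col-0 replicate 2 or mSPL13 replicate 3 (-0.64 to -0.59). The cell division list was not called without Col-0 replicate 3 (adjusted p = 0.101) or mSPL13 replicate 2 (0.0951), nor the expansin list without Col-0 replicate 1 (0.0582), Col-0 replicate 3 (0.0847), mSPL13 replicate 1 (0.056) or mSPL13 replicate 2 (0.0627). The nuclear photosynthesis (median 0.03), heat shock (-0.54), seed oil mobilisation (0.04) and shoot meristem (-0.03) lists had 0 members that passed over all genes, and HSP17.6B and ROF2 were lower when adjusted over the list alone. The seed oil list's mean was negative (-0.04) while its median was positive. Beside these changes, the GAPDH ratio of 3' to 5' signal averaged 1.05 in mSPL13 and 0.977 in Col-0 (exact permutation p = 0.1, adjusted p = 0.3).

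Among the family members named because they were called, EXPB1 (-1.01 ± 0.23) and EXPB3 (-0.93 ± 0.21) fell beside EXPA8 and EXPA15, and EXLB1 rose (0.84 ± 0.12), so that 4 of 12 expansins fell and 1 rose. SWEET3 (1.35 ± 0.21) and SWEET17 (0.78 ± 0.20) rose, of 6 SWEET transporters. UGT84A1 (-1.25 ± 0.23), UGT76C2 (-1.13 ± 0.15) and UGT74D1 (-0.58 ± 0.14) fell, of 27 UDP-glycosyltransferases grouped by symbol, whose set had a camera adjusted p of 0.0455 and adjusted p = 0.468 with an estimated correlation. AT1G01390, AT4G14090 and AT2G31790, glycosyltransferases named above that also fell, are not among the 27. Of the 8 tau-class glutathione transferases, 0 passed over all genes and 4 were lower when adjusted over the list alone (camera adjusted p = 0.0455, and adjusted p = 0.468 with an estimated correlation). The 16 trichome birefringence-like genes had a median of -0.16, with 0 members that passed over all genes and 1 lower when adjusted over the list alone (camera adjusted p = 0.0455, and adjusted p = 0.5 with an estimated correlation). Of the 66 chloroplast-encoded genes, 2 rose, petN (0.95 ± 0.25) and ndhJ (0.91 ± 0.19), ndhJ not without mSPL13 replicate 1 or 3 (0.80 to 0.91), and the median was 0.15 (camera adjusted p = 0.094). The number that rose was 0 without mSPL13 replicate 1 or 3, 1 without Col-0 replicate 2 or 3 or SPL13 replicate 2, and 4 without Col-0 replicate 1 or SPL13 replicate 1.

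Both mSPL13 comparisons called 125 probe sets higher and 105 lower, and 0 in opposite directions. Independent lists of these sizes would share 5.2 and 3.7. With unchanged groups simulated on the same shared arrays, the mean overlap was 0.04 in each direction and the highest 1. Those simulations held no effect in any group. Both comparisons use the same mSPL13 arrays, and neither figure shows how much overlap these shared arrays alone bring to lists of this size. Among the shared probe sets with a gene name, AT4G19430, AT5G55450, OSM34, AT5G55180, AT1G62500, GAT1_2.1, AT1G19530, ndhJ, AT3G13175 and AT3G15450 had the highest mean rise, and AT1G01390, AT5G57760, MSRB6, AT1G67910, AT2G47780, AT1G28600, AT3G59340, AT1G73120, AT5G44580 and AT1G06830 the lowest. With no filter on low signal the overlap was 78 higher and 63 lower. It was 46 and 52 without mSPL13 replicate 1, 75 and 72 without mSPL13 replicate 2, 65 and 52 without mSPL13 replicate 3, 58 and 55 without SPL13 replicate 3, 91 and 65 without SPL13 replicate 1, 76 and 92 without SPL13 replicate 2, and 79 and 72 without Col-0 replicate 2.

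**Figure D3:**
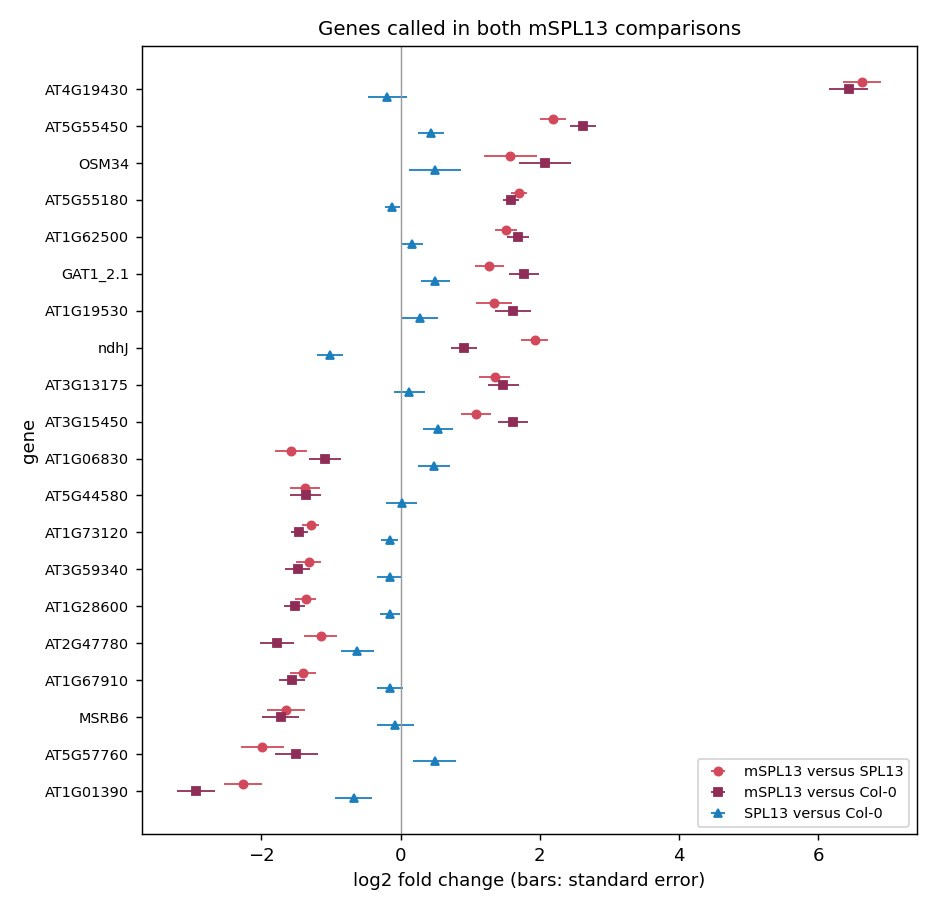
Log2 fold change with its standard error (x axis) in 3 comparisons for the 10 highest and 10 lowest named genes called in both mSPL13 comparisons (y axis). In SPL13 versus Col-0, AT5G55450 lies at 0.43 and AT1G01390 at -0.68, and none of these 20 genes passed the test there.

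The comparison of SPL13 with Col-0 asks what the transgene does while miR156 can still act on it. The chloroplast genes that fell in SPL13 were psbT, rps15 and rpoA: psbT fell from 442 to 74.7 (log2 fold change -2.21 ± 0.31, and -1.57 with the pseudocount at the 40th percentile), rps15, a plastid ribosomal protein gene, fell by 2.30 ± 0.37, and rpoA fell by 0.85 ± 0.13. AFR, an F-box protein of far-red light signalling, fell by 0.91 ± 0.14, from 506 ± 77.6 to 258.2 ± 1.65, and was 276 ± 35.2 in mSPL13. In all, 2 probe sets were higher and 5 lower (limma, adjusted p under 0.05). The other lower one is annotated to several chloroplast genes. The 2 higher ones, singled out after their values were seen, pair with no gene name here. Which gene either detects, the transgene included, is not given in the sources used here. The signal of one was 390 ± 21.2 in Col-0, 1326 ± 147 in SPL13 and 3975 ± 356 in mSPL13 (log2 fold change 1.71 ± 0.12), and that of the other was 750.4 ± 118, 1325 ± 75.8 and 1569 ± 70.5 (0.81 ± 0.12).

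Of the 66 chloroplast-encoded genes, 3 fell over all genes, 58 were lower when adjusted over the list alone, and 0 were positive. The number that fell over all genes was 33 without Col-0 replicate 3, 31 without SPL13 replicate 3, 13 without SPL13 replicate 1 and 8 without mSPL13 replicate 2. It was 0 without Col-0 replicate 1 or 2, SPL13 replicate 2 or mSPL13 replicate 1. The median was -1.33 (camera adjusted p = 1.05e-68, and adjusted p = 0.153 with an estimated correlation). The 4 mitochondrially encoded probe sets, ccb382, nad4, cox1 and orfX, had a median of -1.35 and none passed. The 4 flavonoid genes had a median of -0.76, with 0 members that passed over all genes and 4 lower when adjusted over the list alone (camera adjusted p = 0.000588, and adjusted p = 0.49 with an estimated correlation), beside the low Col-0 replicate 3. The nuclear photosynthesis genes had a median of 0.08, with PRK at 0.27 ± 0.11. The glucosinolate, cell division, expansin, heat shock, root, seed oil and shoot meristem lists were not called, and XTH33 of the expansin list was higher when adjusted over the list alone (0.80 ± 0.26). The 27 UDP-glycosyltransferases grouped by symbol had a median of -0.14, with 0 members that passed (camera adjusted p = 0.000683, and adjusted p = 0.153 with an estimated correlation).

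The calls of psbT, rps15 and rpoA were each lost without Col-0 replicate 1 or 2, SPL13 replicate 2 or mSPL13 replicate 1, and that of AFR also without SPL13 replicate 1 (log2 fold changes of -2.26 to -1.88, -2.50 to -2.04, -0.88 to -0.82 and -0.92 to -0.80). All 4 calls were also lost with no filter on low signal and with eBayes without trend. Those of AFR, rpoA and rps15 were lost on the compared groups only, and those of AFR and rps15 with the replicate number as a block. That of rps15 was also lost with a smaller or no pseudocount, the stricter filter, quantile normalization or array quality weights. The small count in this comparison depends on single arrays and on the test. Without Col-0 replicate 3 it was 46 higher and 102 lower, without SPL13 replicate 3 it was 38 calls in all, without SPL13 replicate 1 it was 16, without mSPL13 replicate 2 it was 12, and without Col-0 replicates 1 and 2, SPL13 replicate 2 and mSPL13 replicate 1 it was 2, 1, 1 and 1. At an unadjusted p under 0.05, 592 probe sets were higher and 613 lower, against 682 expected by chance in both directions together.

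Set against SPL13 and Col-0 together, mSPL13 had 413 probe sets higher and 375 lower (limma, adjusted p under 0.05). AUR1 (0.43 ± 0.11) and the ubiquitin-conjugating enzyme gene UBC20 (0.40 ± 0.11) rose here without passing in either single comparison, and scpl29 (-0.42 ± 0.11), of the serine carboxypeptidase-like family, fell likewise; these family members were chosen after their values were seen. Of 3 cell division genes 2 rose (camera adjusted p = 0.014, 0.0581 without mSPL13 replicate 2, and adjusted p = 0.134 with an estimated correlation), of 3 glucosinolate genes 2 fell (camera adjusted p = 0.0044, and adjusted p = 0.134 with an estimated correlation), and of 4 flavonoid genes 2 fell (camera adjusted p = 0.00491, and adjusted p = 0.254 with an estimated correlation). Of 66 chloroplast-encoded genes 24 rose, and here too the SPL13 arrays set the difference (camera adjusted p = 1.97e-22, and adjusted p = 0.44 with an estimated correlation). NAI2 and SMZ fell, and the nuclear photosynthesis, seed oil, heat shock and shoot meristem lists had 0 members that passed over all genes. The 16 trichome birefringence-like genes had a median of -0.18, with 0 members that passed over all genes (camera adjusted p = 0.0231, and adjusted p = 0.44 with an estimated correlation). The 788 calls became 346, 467 and 357 without mSPL13 replicates 1, 2 and 3.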

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

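The tests of the chloroplast-encoded genes and of AT4G19430 were chosen only after those results were seen, and the other tests in this part were written down beforehand. The control probe set AFFX-r2-At-U12639_at, which is not in the comparisons above, gave 29.7, 3.1 and 2.3 in the Col-0 arrays and at least 25866.7 in each of the 6 transgenic arrays. Of the 64 control probe sets, 1 was separated this far, by over 10-fold in every array. What it detects is not given in the sources used here, and no explanation of it was tested.

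The chloroplast-encoded genes were low in the 3 SPL13 arrays, with a median log2 fold change of -1.33 against Col-0. Without SPL13 replicate 1, the lowest array, the median was -0.884 and 63 of the 66 genes stayed negative, which argues against 1 low array as the whole cause. The nuclear photosynthesis genes had a median of 0.084, which argues against fewer green cells. The 66 genes had a median of 0.152 in mSPL13 against Col-0, which argues against an effect that both transgenes share. The mitochondrially encoded probe sets had a median of -1.348, so a lower yield of organelle transcripts of every kind in the SPL13 RNA or cDNA is a candidate explanation, and a biological change of both organelles in the SPL13 seedlings stays open and untested. The control signals for added bacterial and phage transcripts were also lowest on average in SPL13. For cre the mean was 15100, against 16330 in Col-0 and 16220 in mSPL13 (exact permutation p = 0.1 for each, the smallest that 3 arrays against 3 allow). For bioB it was 308 against 352 and 374 (exact permutation p = 0.2 and 0.1). For dap it was 284 against 397 and 447 (exact permutation p = 0.3 and 0.2). The lowest dap signal, 192.4, was in SPL13 replicate 1. These controls do not measure organelle transcripts, and whether a step in sample handling lowered both was not tested.

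The mSPL13 arrays had the most calls and the highest mean GAPDH 3' to 5' ratio, although SPL13 replicate 2 (1.029) lay above mSPL13 replicate 2 (1.007). Across the 788 probe sets called in mSPL13 versus both other groups, the fold change and the slope on that ratio within groups correlated at r = 0.243. This is across genes, which are not independent replicates. Of 216 shuffles of the ratio within groups, 30 gave a value as high, with a range of -0.395 to 0.388. The value lies within the range of the shuffles, so RNA quality and genotype cannot be told apart for these calls by this test.

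AT4G19430 was on in mSPL13 alone, at 2545.7, 2348 and 2804.3 against at most 29.3 in the other arrays. Its neighbours were taken as the 6 nearest genes, on both sides, that have a named probe set of their own. Any nearer gene without one was not examined. Of these 6 neighbours 2 were tested, and 0 were called higher by limma (AT4G19390 at -0.64, adjusted p = 0.0534, and AT4G19450 at 0.10, adjusted p = 0.682). Neither was higher at an unadjusted p under 0.05. The other 4 neighbours had mean signals of 6.3 to 55.8 in mSPL13, 4.67 to 56.1 in SPL13 and 14.3 to 74.0 in Col-0, and none had its highest mean in mSPL13, but such low signals exclude nothing. With 2 neighbours tested, activation of a chromosome segment next to a transgene insertion and an effect of the SPL13 protein cannot be told apart.

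For each comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split called 414 probe sets for mSPL13 versus SPL13, 596 for mSPL13 versus Col-0 and 7 for SPL13 versus Col-0, and the highest other split called 0 in each; 1 split of 10 reached the real count. For mSPL13 versus both, 1 of 100 splits, drawn of 840, reached 788, a share under 0.05. The highest other split, which keeps the 3 mSPL13 arrays together, called 546. Most splits part these 3 arrays, which moves their difference into the spread within groups and leaves few or no calls. The test therefore cannot separate genotype from anything else that the 3 mSPL13 arrays share.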

How the results depend on the processing

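The fit without the chloroplast-encoded probe sets was chosen only after the result was seen, and the other alternatives were planned. Of 67 named results past the threshold, 1193 of 1314 alternatives kept the call, 121 lost it and 0 reversed it. Of 130 not past it, 26 of 2567 alternatives gained a call and 8 reversed. These tallies of named results, and the lost calls named below, leave out the alternatives with another threshold. Results of lists and families were counted per comparison, leaving out the called lists and the called results of the chloroplast-encoded set. For these 102 results, 35 of 2422 alternatives, the looser thresholds included, were weaker and 67 stronger. The most named calls, 19, were lost with no filter on low signal: psaA, atpF, AT5G62280, OSM34, AT1G19530, AT3G15450 and AT2G47780 in mSPL13 versus SPL13, AT5G61590, AT5G57760, AT1G06830, BCAT4, EXPA8, AT4G14090, DFR and SMZ in mSPL13 versus Col-0, and psbT, rps15, rpoA and AFR in SPL13 versus Col-0. Of the other alternatives that keep all arrays, eBayes without trend ended 6 (OSM34, AUR2, psbT, rps15, rpoA and AFR), the compared groups only 5 (AUR2, SMZ, rps15, rpoA and AFR), the replicate block 4 (AUR2, SMZ, rps15 and AFR), array quality weights 2 (BCAT4 and rps15) and quantile normalization 2 (AUR2 and rps15). The pseudocount at the 10th percentile, none, and the stricter filter ended 1 each (rps15). In all, rps15 was lost in 13 of 20 settings, AUR2 in 12, SMZ in 11, AFR in 9, rpoA in 7 and psbT in 6. With no filter on low signal, more probe sets are tested, and mSPL13 versus SPL13 had 145 higher and 91 lower, mSPL13 versus Col-0 176 lower, SPL13 versus Col-0 1 higher and 0 lower (limma), mSPL13 versus both 231 lower, and the overlap was 78 and 63. Array quality weights gave 394 and 294 for mSPL13 versus SPL13. The lower count of SPL13 versus Col-0, 5 as reported, was 12 with the pseudocount at the 40th percentile, 3 with the stricter filter, 3 with quantile normalization, 9 with median centring, 3 with array weights, 0 without trend (1 higher), 1 on the compared groups only (1 higher) and 2 without the chloroplast-encoded probe sets; the cause was not tested. At an adjusted p under 0.10 the counts were 410 and 327, 539 and 572, 4 and 35, and 734 and 678 (mSPL13 versus SPL13, mSPL13 versus Col-0, SPL13 versus Col-0, mSPL13 versus both), with overlaps of 218 and 196. With at least 2-fold they were 87 and 28, 58 and 68, 1 and 3, and 74 and 48, with overlaps of 27 and 24. At an unadjusted p under 0.05 they were 1172 and 1103, 1432 and 1304, 592 and 613, and 1500 and 1401, with overlaps of 661 and 637. With an estimated correlation no list was called: mSPL13 versus SPL13 glucosinolate and cell division 0.214 and chloroplast 0.329; mSPL13 versus Col-0 glucosinolate, cell division, expansins and flavonoid 0.131 and root markers 0.138; SPL13 versus Col-0 flavonoid 0.488 and chloroplast 0.153; mSPL13 versus both glucosinolate and cell division 0.134, flavonoid 0.254 and chloroplast 0.438. Leaving out 1 array at a time gave 120 to 275 higher and 72 to 193 lower for mSPL13 versus SPL13, 119 to 453 and 129 to 450 for mSPL13 versus Col-0, 1 to 46 and 0 to 102 for SPL13 versus Col-0, 160 to 460 and 166 to 424 for mSPL13 versus both, and overlaps of 46 to 131 and 52 to 111. The totals that moved most were 200 for mSPL13 versus SPL13 without mSPL13 replicate 3, 248 and 903 for mSPL13 versus Col-0 without Col-0 replicates 2 and 3, 148 for SPL13 versus Col-0 without Col-0 replicate 3, and 346 for mSPL13 versus both without mSPL13 replicate 1. Adjusted p ranged from 0.00563 to 0.0807 for glucosinolate in mSPL13 versus SPL13, from 0.0117 to 0.0794, 0.0288 to 0.101 and 0.0113 to 0.0581 for cell division against SPL13, Col-0 and both, and from 0.0313 to 0.0847 for expansins in mSPL13 versus Col-0. The sign reversed on leaving out an array in SPL13 versus Col-0 for AT1G19530 (-0.000973 to 0.6558), AT4G19430 (-0.3933 to 0.1846), MSRB6 (-0.3907 to 0.1976), AT5G44580 (-0.2591 to 0.2403), AT3G13175 (-0.1146 to 0.3169) and COR47 (-0.2533 to 0.08031), in mSPL13 versus SPL13 for XTH18 (-0.3017 to 0.01819) and in mSPL13 versus Col-0 for a dehydration list probe set of several genes (-0.1227 to 0.2184), none of them called. The replicate number as a block gave 257 and 174, 295 and 329, 3 and 5, and 417 and 382. It kept 379 of 414, 534 of 596, 4 of 7 and 707 of 788 calls. Residuals correlated at -0.06 to 0.149 for pairs of arrays with the same number, above 0.1 in 3 of 9. For different numbers the range was -0.16 to 0.197. The ranges overlap, so this check does not settle whether the numbers pair the arrays. AT4G19430 has no value with the pseudocount at the 10th percentile, with none and with the stricter filter, where it was not among the probe sets tested. A fit on the compared groups only has no separate value for mSPL13 versus both. The scalings moved the median of all genes by at most 0.0143.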

Other observations

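The genes named in this part were chosen after their values were seen, and the lists of sugar starvation, hypoxia and mitosis genes were composed after the calls in both mSPL13 comparisons were seen. MCCA, IVD and ETFQO, which act in leucine breakdown, rose in mSPL13 against both SPL13 and Col-0, with log2 fold changes of 0.88 and 1.21, 0.55 and 0.66, and 0.67 and 0.56. MCCB (0.46 and 0.37) and AT2G26800 (0.04 and -0.005) did not pass in either comparison, so this is not shown for the pathway. AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, rose by 0.67 and 1.11, and SWEET3 by 1.08 and 1.35. The mitotic genes 3xHMG-box1 (0.77 and 0.73), FU (0.75 and 1.05), the kinesin KICP-02 (0.68 and 0.63) and SOL1 (0.57 and 0.54) rose in both, while BUBR1 (0.49 and 0.21), HTR12 (0.27 and -0.04) and UBC19 (-0.05 and -0.02) passed in neither. Of the 17 tested genes of the mitosis list, 10 rose in both, but the list was composed with those calls in view, so the tally does not test the group.

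AT3G10020 (0.94 and 1.16), AT4G10270 (0.93 and 1.25) and AT1G33055 (0.67 and 1.18), which respond to low oxygen, were also higher in both. Of the 11 tested genes of the hypoxia list, 5 were higher in both, a tally that does not test the group either. AT1G72940 (-0.392 and -0.645) and AT1G05575 (-0.25 and -0.316) of that list passed in neither. The homeodomain gene HAT2 (-0.87 and -1.11), the Aux/IAA gene IAA20 (-1.20 and -1.31), the chalcone isomerase-like gene CHIL (-0.69 and -0.84) and the allantoinase ALN (-0.61 and -0.69) were lower in both. SPCH, which starts the stomatal lineage, rose against Col-0 (1.12) and against both groups together (0.89, limma adjusted p = 0.00439), and did not pass against SPL13 (0.66, limma adjusted p = 0.0638).

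Whether these genes stand for their processes was examined in mSPL13 versus both on the list members whose calls had not been seen. None of these members was called higher in both single comparisons. The 4 unseen sugar starvation genes had a median of 0.04 (upper quartile 0.151), and 1 rose, MCCB (0.42). The 6 unseen hypoxia genes had a median of 0.103 (upper quartile 0.343), and 1 rose, AT3G27220 (0.80). The 4 unseen mitosis genes had a median of 0.233, and 1 rose, KINESIN-12B (0.61). In the other comparisons, which the test had not named, the same 4 genes had a median of 0.38 in mSPL13 versus SPL13 (camera adjusted p = 0.0393, and unadjusted p = 0.0723 with an estimated correlation), 0.10 in mSPL13 versus Col-0 (camera adjusted p = 0.636) and -0.30 in SPL13 versus Col-0 (camera adjusted p = 0.0495, and unadjusted p = 0.08 with an estimated correlation). The bound written beforehand against a group effect, an upper quartile under 0.25, was met by the sugar starvation list. A minimum of 5 unseen members for excluding anything was set only after that result was seen. The reason is that the list leaves out its called genes and keeps 4 others, so that bound was wrong for so short a remainder. In mSPL13 versus both, none of the 3 medians passed the limit of 0.25 that a group effect needed. In all 3 lists the remainder lacks the members called higher in both comparisons, which lowers its median whether or not a group effect exists. The medians therefore cannot decide, and a group effect may exist or not in each.

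If the non-mutated transgene moves the same genes weakly, the SPL13 arrays should lie on the mSPL13 side of Col-0 at genes called without the Col-0 array they are compared with. With each Col-0 array held out in turn, 66.4% of 327, 75.3% of 247 and 54% of 902 called probe sets lay on the mSPL13 side, with the chloroplast-encoded ones left out because they are low in the SPL13 arrays. The lowest share, with Col-0 replicate 3 held out, is near an even split, so a weak effect of the non-mutated transgene on these genes could be present or absent.

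Called genes of mSPL13 versus both were not direct neighbours more often than shuffled calls. Of 372 called among 7145 tested genes with a neighbour relation, 9 neighbouring pairs were called in the same direction, against a mean of 9.6 when the calls were shuffled, and 623 of 1000 shuffles gave as many. The count covers only directly adjacent tested genes with a name, so clusters with gaps would not show in it.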
